A study of Mus musculus with 23 samples.

How the data were processed

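The series holds ATAC-seq of NeuN-positive dentate gyrus nuclei from 2 mouse models of Kabuki syndrome and wild types, 23 libraries in all. The values used are the deposited raw counts of reads per peak and library, whole numbers that were not normalized, over 1 set of 172558 peaks shared by all libraries. Per the submitters' processing notes, Picard, SAMtools, MACS2 and featureCounts were used and the genome build was mm10; versions, the aligner, the filters on duplicates and the shift of reads for the transposase are not given in the sources used here. The way in which libraries were pooled for peak calling is likewise not given in the sources used here. If peaks were called on pooled libraries, regions open in few libraries can be missed, and counts in peaks cannot show a change of accessibility shared by all peaks. Peaks were 199 to 5043 bp wide (median 612 bp) and covered 126 Mb.

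Group and replicate number of each library came from the sample titles and the genotype labels, and the titles also assign each wild type to the KS1 or the KS2 comparison. The prefix of the library code in the title (9, 9_2, 10-5 or 8), called the cohort here, can mark a round of work. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom of each pair was at least 1.16. This does not tell separate animals from repeat libraries of 1 animal, and all 23 libraries were treated as separate samples.

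No genome sequence was used, and gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, without strand. The plan had been to sort peaks into promoters and CpG islands with a genome sequence and to make no classes without one. In its place, and after the data were seen, peaks were classed by position as gene end (17444 peaks within 1000 bp of either end of 1 of 21887 protein-coding genes), gene body (85958) or intergenic (69156). A gene-end peak can therefore lie at the start or at the end of a gene, and CpG islands and aging-related regions, which the series title names, were not analysed here. Of 14956 genes with an end peak, 4329 had a peak at both ends. For gene lists each gene was represented by its end peak with the highest mean count over all libraries, so neighbouring genes can share a peak. Of the 671 genes of the 24 lists, 669 matched the table and 573 had an end peak.

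Counts were tested with edgeR 4.0.16 in R 4.3.3: the filterByExpr filter, TMM scaling, robust dispersions and the quasi-likelihood F test with cohort and genotype as terms, with Benjamini-Hochberg adjustment over all tested peaks and calls at an adjusted p under 0.05. The KS1 comparison used 13 libraries and the KS2 comparison 10. All KS2 libraries belong to cohort 10-5, so the wild types of cohort 8 inform the spread but not the KS2 difference. The difference between KS1 and KS2 was a contrast in 1 fit of all 23 libraries. Standard errors of log2 fold changes follow from the F statistic. Means and SD are of TMM-scaled counts per 1e6 (CPM) over all libraries of a group, cohorts together, while fold changes compare within cohorts. Gene lists, classes and chromosome X were tested with camera (preset correlation 0.01 and, beside it, an estimated correlation) and fry from limma 3.58.1; lists were adjusted over the 24 lists. Overlaps used Fisher's exact test. Text and tables were prepared with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

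Tests, covariates, gene lists, the rule for named peaks and all alternatives not marked otherwise were fixed before the data were examined. The rule names called gene-end peaks (the 10 with the smallest p in each direction, or the 5 smallest where none passed), the 3 called other peaks with the smallest p in each direction, the 5 peaks with the smallest p in each direction, the 3 members of each list with the smallest p, the 5 largest differences in each direction, Kmt2d and Kdm6a. A few genes that the rule names are not reported here. It was written for promoters and, in case of no genome, for coordinates alone; both branches were applied, with gene ends in place of promoters. The called peaks inside Nell2 and Vdr and the peak 12124 bp from Onecut1 fall outside it and were named after their values were seen, as was Onecut1 in KS2 as a case of its own.

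Alternatives were a fit without the cohort, the replicate number as a block, 2 surrogate variables (sva 3.50.0), the log2 total count as a covariate, 1 cohort alone, DESeq2 1.42.0, limma-voom with cyclic loess, RLE and total-count scaling, no filter, a mean count of 20 or more, autosomal peaks alone, an adjusted p under 0.1, gene ends within 2000 bp, counts summed per gene, and each library left out. Alternatives added after the data were seen were the share of counts in the most accessible 10% of peaks as a covariate, the same share among peaks away from gene ends, and the interaction of cohort and genotype. Corrections for GC content and other CpG island definitions were not run, for lack of a sequence. DESeq2 left the adjusted p of 142116 peaks in KS1 empty through its filter on low means, and these were not counted as tested.

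The tests were run on simulated counts with the real means, library sizes and dispersions. For KS1, over 166596 peaks, edgeR recovered 11.9%, 59.7% and 98.5% of peaks changed by log2 of 0.5, 1 and 2. For KS2, over 164407 peaks, it recovered 0%, 17.9% and 62.1%, and for the difference, over 171729 peaks, 0%, 7.46% and 57.6%. Of the calls made, 11.5% (KS1), 11.5% (KS2) and 8.51% (difference) were peaks that had not been changed, above the nominal rate, while 4.83%, 4.80% and 4.85% of unchanged peaks had an unadjusted p under 0.05. A list shifted by log2 of 0.5 came back at 0.47 (KS1) and 0.49 (KS2) and no other list was called. A shift of chromosome X by 0.3 came back at 0.30 in both. Peaks were simulated independently of each other, without cohort effects or differences in enrichment between libraries. The simulation therefore cannot show how often lists of correlated peaks are called falsely. Total counts of 6.59 to 19.4 M over 172558 peaks leave a median of 19 to 57 reads per peak and library, so small changes at single peaks lie under the counting error.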

Results

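Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase places sequencing adapters into open DNA, in neuronal nuclei of the mouse dentate gyrus. Nuclei carrying the neuronal protein NeuN were sorted from microdissected tissue of C57BL/6J mice, with 5000 nuclei for most samples, and the sort leaves glia out. Both disease models are of Kabuki syndrome, a developmental disorder with intellectual disability. In the type 1 model (KS1) 1 copy of Kmt2d, whose protein methylates lysine 4 of histone H3, carries a β-geo insertion. In the type 2 model (KS2) 1 copy of Kdm6a, the X-linked gene of a demethylase of lysine 27 of histone H3, is lost. There were 8 KS1 libraries with 5 wild-type libraries of their own, and 4 KS2 libraries with 6 other wild-type libraries. The codes in the sample titles put the libraries into 4 cohorts. Cohort 9 held 4 KS1 and 3 wild-type libraries, cohort 9_2 held 4 KS1 and 2 wild-type libraries, cohort 10-5 held 4 KS2 and 3 wild-type libraries, and cohort 8 held 3 wild-type libraries of the KS2 comparison alone. Reads were counted in 172558 peaks, and the total count per library ran from 6.59 to 19.4 M (M, 1e6 counts). The total was 11.9 ± 2.98 M in KS1 (SD, n = 8), 11.7 ± 5.11 M in its wild types (n = 5), 9.11 ± 3.06 M in KS2 (n = 4) and 10.6 ± 4.64 M in its wild types (n = 6). The labels do not say that libraries come from separate animals, so p-values measure the spread between these samples.

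At the mutated genes themselves, no peak passed the test over all peaks in either mutant. The peak at an end of Kmt2d (chromosome 15, 98830674 to 98831937, shared with Prkag1) had 16.9 ± 2.91 scaled counts (CPM) in KS1 (SD, n = 8) against 14.0 ± 0.874 in wild type (n = 5), a log2 fold change of 0.23 (SE 0.10, edgeR adjusted p = 0.343). The peak at an end of Kdm6a (chromosome X, 18161599 to 18163853) had 101 ± 8.39 CPM against 81.3 ± 12.5, a log2 fold change of 0.33 (SE 0.10, edgeR adjusted p = 0.121). In KS2 the Kmt2d end peak had a log2 fold change of 0.26 (SE 0.19, edgeR adjusted p = 1.00) and the Kdm6a end peak 0.19 (SE 0.13, edgeR adjusted p = 1.00); over the alternatives these ran from 0.15 to 0.57 and from 0.055 to 0.34 without passing. Of the peaks along each gene, edgeR called 0 of 8 at Kmt2d and 0 of 5 at Kdm6a in KS1, where 3 and 2 had an unadjusted p under 0.05. Of these 8 and 5 peaks, 4 and 2 were higher. The smallest p at Kmt2d belonged to a peak classed as gene body, 98871359 to 98872741 (log2 0.34, SE 0.10, edgeR adjusted p = 0.129). It lies near the other end of the gene, whose coordinates are 98831669 to 98874077. As strand was not used, it was not settled which of these peaks is at the start of Kmt2d. Adjusted over each gene's peaks alone, the smallest p in KS1 was 0.0136 at Kmt2d and 0.00652 at Kdm6a (from the edgeR p). In KS2 edgeR called 0 of 8 and 0 of 6, and none had an unadjusted p under 0.05. In KS1 the Kdm6a end peak passed in 3 alternatives, among them DESeq2 (log2 fold change 0.33), and did not pass in 12. Accessibility of a gene is not its expression, so these values do not check the genotype labels.

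The first comparison asked where chromatin is more or less open in neurons with the Kmt2d mutation. In KS1, 16 of 166596 tested peaks passed, 14 with higher and 2 with lower accessibility than in wild type. The smallest p belonged to the peak at an end of Camk2d, the delta subunit of a calcium- and calmodulin-dependent kinase (chromosome 3, 126595989 to 126598398). It rose from 19.9 ± 2.27 CPM in wild type (SD, n = 5) to 37.4 ± 5.73 CPM in KS1 (n = 8), a 1.85-fold change (log2 0.89, SE 0.11, edgeR adjusted p = 6.1e-06). The 7 peaks at gene ends that passed were all higher. After Camk2d came Zfp521, a zinc finger transcription factor (log2 0.68, SE 0.12, edgeR adjusted p = 0.00843), Onecut1, a homeodomain transcription factor (log2 0.61, SE 0.11, edgeR adjusted p = 0.0118), Foxp2, a forkhead transcription factor tied to speech (log2 0.59, SE 0.11, edgeR adjusted p = 0.0165), and Adgrl2, a latrophilin of the synapse (log2 0.57, SE 0.11, edgeR adjusted p = 0.0223). The others were Fbn2, a fibrillin of extracellular microfibrils (log2 0.56), and Ube2e3, a ubiquitin-conjugating enzyme (log2 0.54). Each of these 7 peaks was higher in 8 of 8 KS1 libraries than the wild-type mean of its cohort. For Onecut1 the means were 22.1 CPM in KS1 and 14.5 ± 1.71 CPM in wild type.

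**Figure D1:**
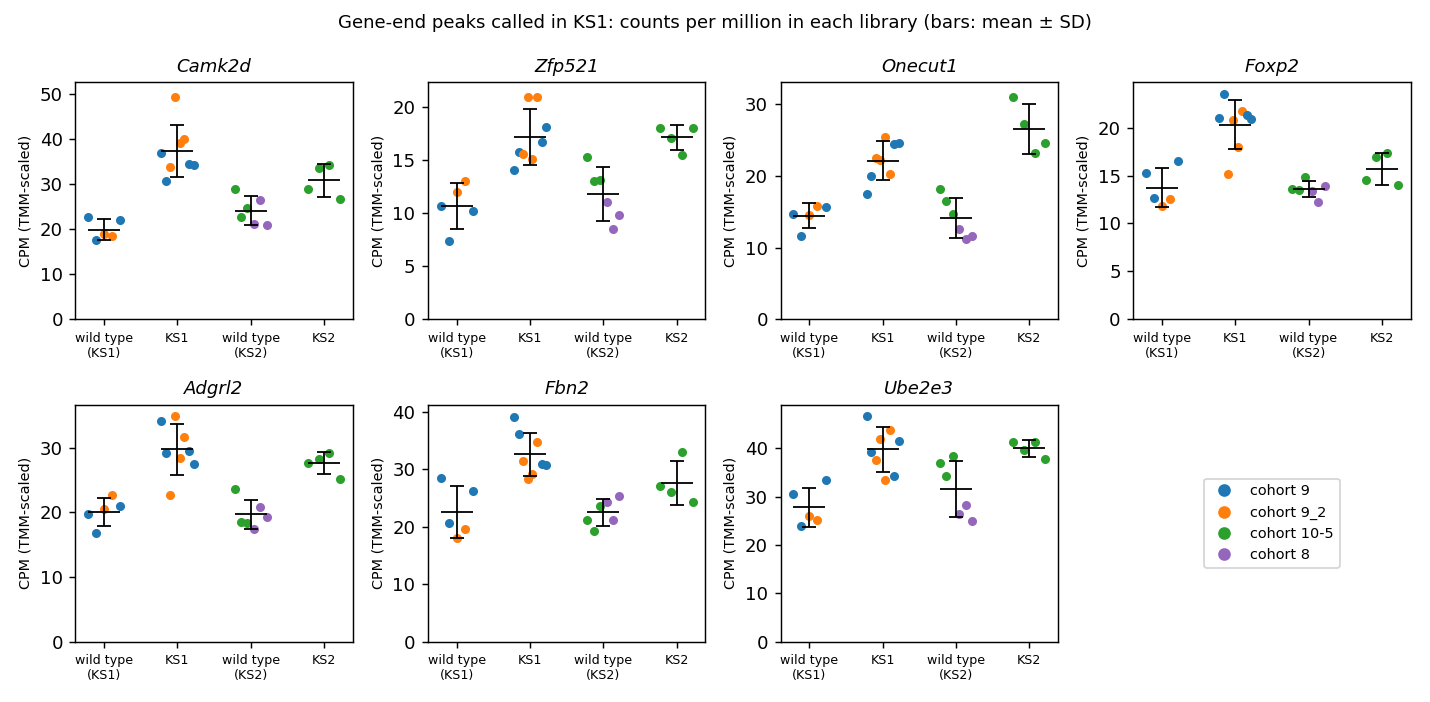
TMM-scaled counts (CPM, vertical axis) in each library of the 4 groups (horizontal axis) for the 7 gene-end peaks that passed in KS1; points are libraries coloured by cohort and bars are means with SD. Camk2d had a mean of 37.4 CPM in KS1 and 19.9 CPM in its wild types, and Onecut1 had higher means in both mutants than in their wild types.

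Peaks away from gene ends passed in both directions. The largest fold belonged to a peak on chromosome 15 (79205038 to 79205457) inside a long noncoding RNA gene, 23683 bp from Pick1, at 2.70 CPM in KS1 and 0.873 CPM in wild type (log2 1.64, SE 0.28, edgeR adjusted p = 0.00843). A pair of peaks on chromosome 6 (68152171 to 68152939 and 68339394 to 68341022) rose by log2 1.11 (SE 0.15, edgeR adjusted p = 0.00014) and 0.77 (SE 0.13, edgeR adjusted p = 0.00843). Both lie in the immunoglobulin kappa locus of antibody light chains, over pseudogenes of variable segments. A peak between Arid2 and Scaf11 (chromosome 15, 96408525 to 96409505), 2193 bp from an end of the splicing factor gene Scaf11, rose by log2 0.78 (SE 0.12, edgeR adjusted p = 8.9e-04). A peak 12124 bp from Onecut1 (chromosome 9, 74848466 to 74849797) rose by log2 0.80, and peaks inside Nell2, a secreted neuronal glycoprotein, and inside Vdr, the vitamin D receptor, rose by log2 0.71 and 0.64. The peaks that fell lie inside Abcd2, a peroxisomal fatty acid transporter (chromosome 15, 91165003 to 91165506, log2 -0.92, SE 0.16, edgeR adjusted p = 0.0118), and inside Asxl3, a Polycomb-associated gene (chromosome 18, 22482535 to 22483303, log2 -1.12, SE 0.21, edgeR adjusted p = 0.0344). Both were lower in 8 of 8 KS1 libraries. Next in rank among lower peaks, and not past the test, were peaks near Mobp, a myelin protein (log2 -0.68, edgeR adjusted p = 0.0530), near Mical2 (log2 -0.72) and inside Cars2 (log2 -1.12). Among peaks at gene ends, none that was lower passed. The smallest p among them belonged to Mybpc3 (log2 -0.50, edgeR adjusted p = 0.0925), Wdfy3, an autophagy scaffold (log2 -0.49), Nfe2 (log2 -0.56), Tcte1 (log2 -0.46) and Asz1 (log2 -0.65). Of the 16 peaks that passed, 5 lie on chromosome 15 within 20 Mb of Kmt2d: those near Pick1 and Scaf11 and inside Nell2, Vdr and Abcd2.

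**Figure D2:**
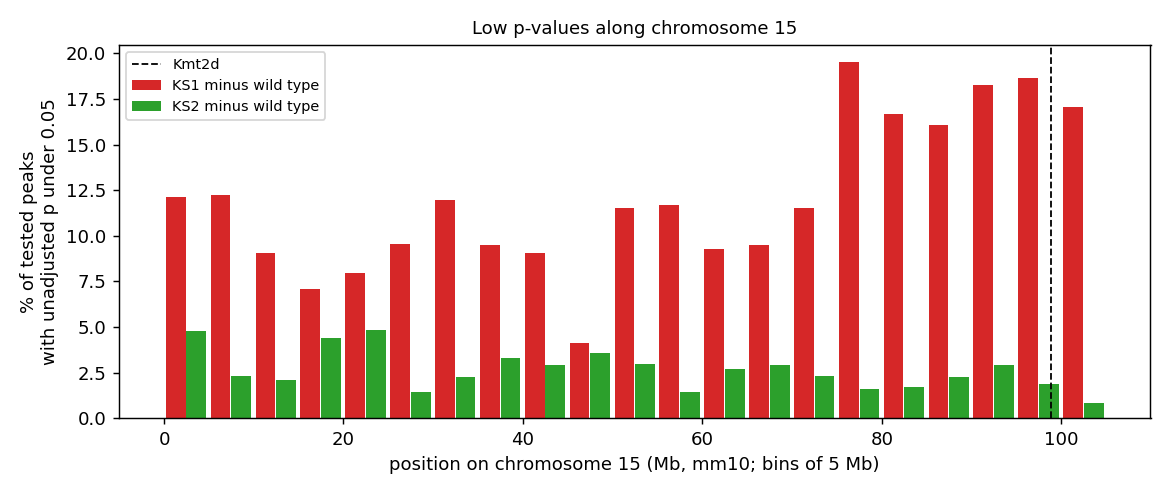
Percent of tested peaks with an unadjusted p under 0.05 (vertical axis) in bins of 5 Mb along chromosome 15 (horizontal axis, Mb) in KS1 and KS2; the dashed line marks Kmt2d. In KS1 the bins from 75 Mb on held 16.1% to 19.5% and those before 4.13% to 12.3%.

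Within the cohorts, on which the peaks were also called, the log2 fold changes had the pooled direction. For Camk2d the log2 fold change was 0.73 in cohort 9 and 1.09 in cohort 9_2, for Onecut1 0.64 and 0.56, for Adgrl2 0.67 and 0.42, and for Abcd2 -1.03 and -0.80. The count varied widely: edgeR called 0 peaks in cohort 9 (8554 with an unadjusted p under 0.05) and 9109 in cohort 9_2 (6471 higher, 2638 lower), and a test of the difference between the cohorts called 272 peaks. Leaving out 1 library moved the count of 16 to 691, 9 or 1413 (without KS1 replicate 2, 6 or 7) and to 5, 3, 5, 8 or 1291 (without wild-type replicate 1, 2, 3, 4 or 5). Scaling by the total count gave 10 higher and 5 lower peaks, limma-voom with cyclic loess 2 higher and 0 lower, and DESeq2 5999 higher and 23 lower. The DESeq2 count was adjusted over fewer peaks, as its filter on low means left 142116 of 166596 without an adjusted p. At an unadjusted p under 0.05, DESeq2 had 17518 peaks and edgeR 20338. Counts summed per gene, over all peaks of a gene and 2000 bp on either side, are other units than single peaks. In that setting 4 genes were called, 0 higher and 4 lower.

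Peaks at gene ends as a class were more open in KS1. Of the 17344 peaks within 1000 bp of an end of a protein-coding gene, 78.9% had a positive fold change, and their median log2 fold change lay 0.22 above that of the other peaks (camera p = 1.0e-35, p = 0.00583 with an estimated correlation). The excess was 0.12 in cohort 9 (camera p = 2.3e-10) and 0.36 in cohort 9_2 (camera p = 9.6e-34), each at the preset correlation of 0.01. At an adjusted p under 0.1, edgeR called 758 peaks, 657 higher and 101 lower, and 503 of them were gene-end peaks, of which 500 were higher. That count ran from 4 without wild-type replicate 2 to 5110 without KS1 replicate 7. Peaks in gene bodies lay 0.059 below the others (camera p = 0.00318, p = 0.00145 with an estimated correlation), and intergenic peaks 0.013 below (camera p = 0.129, p = 0.04999 with an estimated correlation). The most accessible 10% of peaks held 48.6 ± 2.33% of the counts in KS1 (SD, n = 8) and 44.8 ± 1.10% in wild type (n = 5). By cohort these shares were 46.7 ± 1.73% and 45.1 ± 1.34% in cohort 9, and 50.4 ± 0.910% and 44.2 ± 0.313% in cohort 9_2. With that share as a covariate, an alternative added after the data were seen, the gene-end excess was 0.019 (camera p = 0.227 at the preset correlation) and edgeR called 0 peaks (8121 with an unadjusted p under 0.05). The 16 called peaks kept their direction under that covariate, 5 of them with a larger fold, and their standard errors grew by 1.05 to 1.56 times. Camk2d went from 0.89 (SE 0.11) to 0.56 (SE 0.11), Onecut1 from 0.61 (SE 0.11) to 0.68 (SE 0.14) and Ube2e3 from 0.54 (SE 0.10) to 0.25 (SE 0.11). With cyclic loess the gene-end excess was 0.062 (camera p = 7.0e-06 at the preset correlation).

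**Figure D3:**
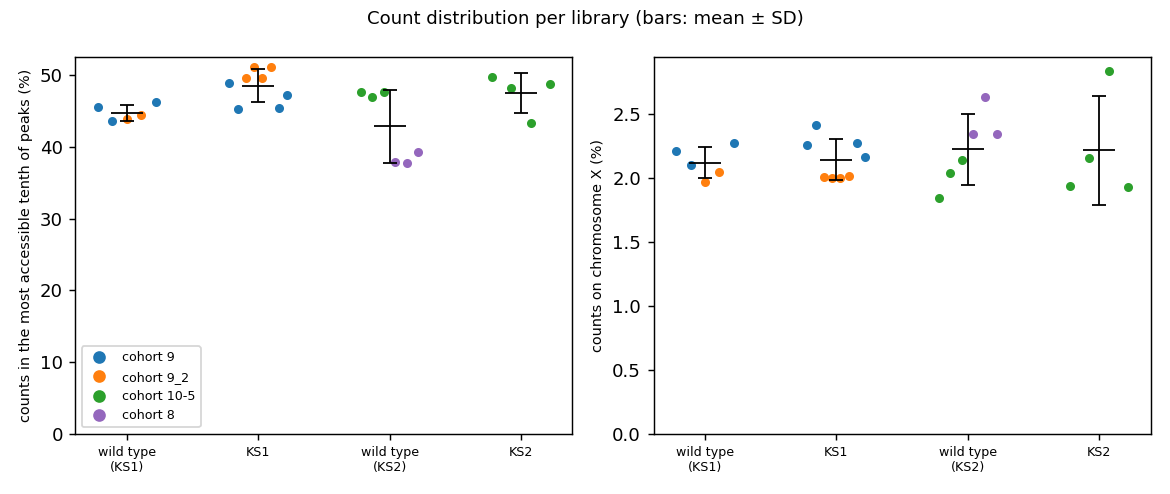
Share of each library's counts in the most accessible 10% of peaks (left panel, %) and on chromosome X (right panel, %) by group; points are libraries coloured by cohort and bars are means with SD. In cohort 9_2 the KS1 libraries lay between 49.6% and 51.2% and the wild types between 44.0% and 44.4%.

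Gene lists were then set against all genes with an end peak, whose median log2 fold change was 0.23. Of 24 lists fixed before the data were examined, 6 had higher and 4 lower fold changes than other genes in KS1 by camera at an adjusted p under 0.05, at the preset correlation. With an estimated correlation none passed (lowest adjusted p = 0.635). Over all 24 lists, 537 of 571 members were higher and 297 passed adjusted over their list alone. The counts of higher and passing members of a list are to be read against these shares. No end peak of a member of the 6 higher lists passed over all peaks. These counts leave out other peaks of a gene: the called peak inside Asxl3, a chromatin regulator of the lists, was lower (log2 -1.12). Of the chromatin regulators of other Mendelian disorders 38 of 38 were higher and 33 passed adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00169, adjusted p = 0.808 with an estimated correlation). Among them were Chd7, the CHARGE syndrome remodeller (log2 0.44, SE 0.10), Setd2, a methyltransferase of lysine 36 of histone H3 (0.44, SE 0.10), and Smarca4, the ATPase of BAF complexes (0.39, SE 0.10). Genes induced by neuronal activity were higher in 27 of 27 cases, 23 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.00484, adjusted p = 0.808 with an estimated correlation). Examples were Homer1, a postsynaptic scaffold (0.41), Fosl2 (0.41) and Egr1, an immediate early transcription factor (0.37). Of the cyclic nucleotide and MAPK signalling genes 30 of 30 were higher, 24 adjusted over the list alone, with Braf (0.39), Sos1 (0.40) and Map2k1 (0.40) in front (camera adjusted p = 0.00484, adjusted p = 0.808 with an estimated correlation). Circadian clock genes were higher in 18 of 18 cases, 15 adjusted over the list alone, such as Clock (0.41), Bhlhe40 (0.40) and Cry2 (0.34) (camera adjusted p = 0.0212, adjusted p = 0.808 with an estimated correlation). Glycolysis and hypoxia genes were higher in 26 of 26 cases, 19 adjusted over the list alone, such as Pdk3 (0.38), Kdm3a (0.40) and Aldoa (0.37). Ribosomal protein genes were higher in 48 of 49 cases, 32 adjusted over the list alone, such as Rplp0 (0.41) and Rps6 (0.36). For these last lists camera gave an adjusted p = 0.0319 each, and an adjusted p = 0.808 with an estimated correlation.

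The lists below the rest still had positive medians. Developmental transcription factors that are Polycomb targets had a median of 0.17, with 14 of 21 higher and 1, Onecut1, past the test both over all peaks and adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.808 with an estimated correlation); Msx1 (0.42) and Twist1 (0.32) followed without passing. The direction of this list turned with the setting: camera placed it above other genes with the top-peak share as a covariate (median 0.19, adjusted p = 0.0189 at the preset correlation), in cohort 9 (median 0.24, adjusted p = 0.153) and with cyclic loess (median 0.25, adjusted p = 0.561), and below them in cohort 9_2 (median 0.045, adjusted p = 7.6e-07). Endothelial and mural markers had a median of 0.048, with 5 of 8 higher (camera adjusted p = 0.0212, adjusted p = 0.635 with an estimated correlation), and Egfl7 was at -0.33 without passing. Interferon and antigen presentation genes had a median of 0.12, with 12 of 15 higher, such as B2m (0.25) (camera adjusted p = 0.0212, adjusted p = 0.808 with an estimated correlation). Microglia markers had a median of 0.085, with 4 of 6 higher (camera adjusted p = 0.0390, adjusted p = 0.808 with an estimated correlation). Of these last 3 lists, none had a member that passed in edgeR over all peaks or adjusted over the list alone; 1, 4 and 0 members had an unadjusted p under 0.05. Median and camera direction thus differed in sign for all 4, because camera sets a list against the other genes.

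The remaining 14 lists did not pass. Of KMT2D and KDM6A complex members 8 of 8 were higher and 5 passed adjusted over the list alone, among them Kmt2c, the closest relative of Kmt2d (log2 0.43, SE 0.10), Kdm6a (0.33) and Wdr5 (0.35). Other H3K4 and H3K27 regulators were higher in 23 of 24 cases, 16 adjusted over the list alone, such as Wdr82 (0.40), Jarid2 (0.38) and Ezh2, the Polycomb methyltransferase (0.37). Nutrient-sensing and longevity genes were higher in 32 of 32 cases, 16 adjusted over the list alone, with Sirt1 (0.42), Igf1r (0.42) and Foxo3 (0.38), and a camera adjusted p = 0.0505. Among synaptic genes, 23 of 34 glutamate receptor and postsynaptic genes passed adjusted over the list alone, 22 of them higher, such as Gria4 (0.42) and Grin2b (0.33), as did 16 of 30 presynaptic genes, such as Pclo (0.36) and Rims2 (0.34), and 15 of 31 ion channel genes, such as Kcnma1 (0.42) and Cacna1a (0.41). With counts summed per gene, camera placed postsynaptic genes (median -0.057, adjusted p = 0.0200) and ion channel genes (median -0.077, adjusted p = 5.6e-04) below other genes, at the preset correlation. In that setting activity-induced genes (median 0.13, camera adjusted p = 7.4e-08), ribosomal protein genes (0.083, adjusted p = 1.5e-04), circadian clock genes (0.073, adjusted p = 0.0200) and microglia markers (-0.23, adjusted p = 0.0195) still passed, and other H3K4 and H3K27 regulators (0.093, adjusted p = 0.0191) and respiratory chain genes (0.066, adjusted p = 0.0432) passed as well. The remaining lists lost their call there: chromatin regulators of other disorders (0.055, adjusted p = 0.0602), glycolysis and hypoxia genes (0.027, adjusted p = 0.0602), cyclic nucleotide and MAPK signalling genes (-0.017, adjusted p = 0.862), developmental transcription factors (-0.021, adjusted p = 0.862), endothelial and mural markers (-0.046, adjusted p = 0.215) and interferon and antigen presentation genes (-0.055, adjusted p = 0.572). Of 43 respiratory chain genes 43 were higher and 15 passed adjusted over the list alone, and of 30 DNA repair and cell cycle genes 30 were higher and 13 passed, such as E2f1 (0.50) and Parp1 (0.38). Dentate granule cell markers were higher in 19 of 19 cases with 8 past adjusted over the list alone, inhibitory neuron markers in 18 of 19 with 8, mossy cell and CA pyramidal markers in 15 of 18 with 9 (8 higher), and immature neuron genes in 19 of 21 with 4. Astrocyte markers were higher in 10 of 13 cases, with 1 past adjusted over the list alone (Slc1a2, 0.33), and oligodendrocyte lineage markers in 9 of 11, with 1 (Ugt8a, 0.52). By fry, which asks only whether a list moves 1 way, 18 of the 24 lists were higher at an adjusted p under 0.05. Within cohorts 4 lists (cohort 9) and 5 lists (cohort 9_2) passed camera, and the count of 10 fell to 5 without wild-type replicate 3, to 0 with cyclic loess and to 1 with the top-peak share as a covariate, which was the list of developmental transcription factors, then above other genes.

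**Figure D4:**
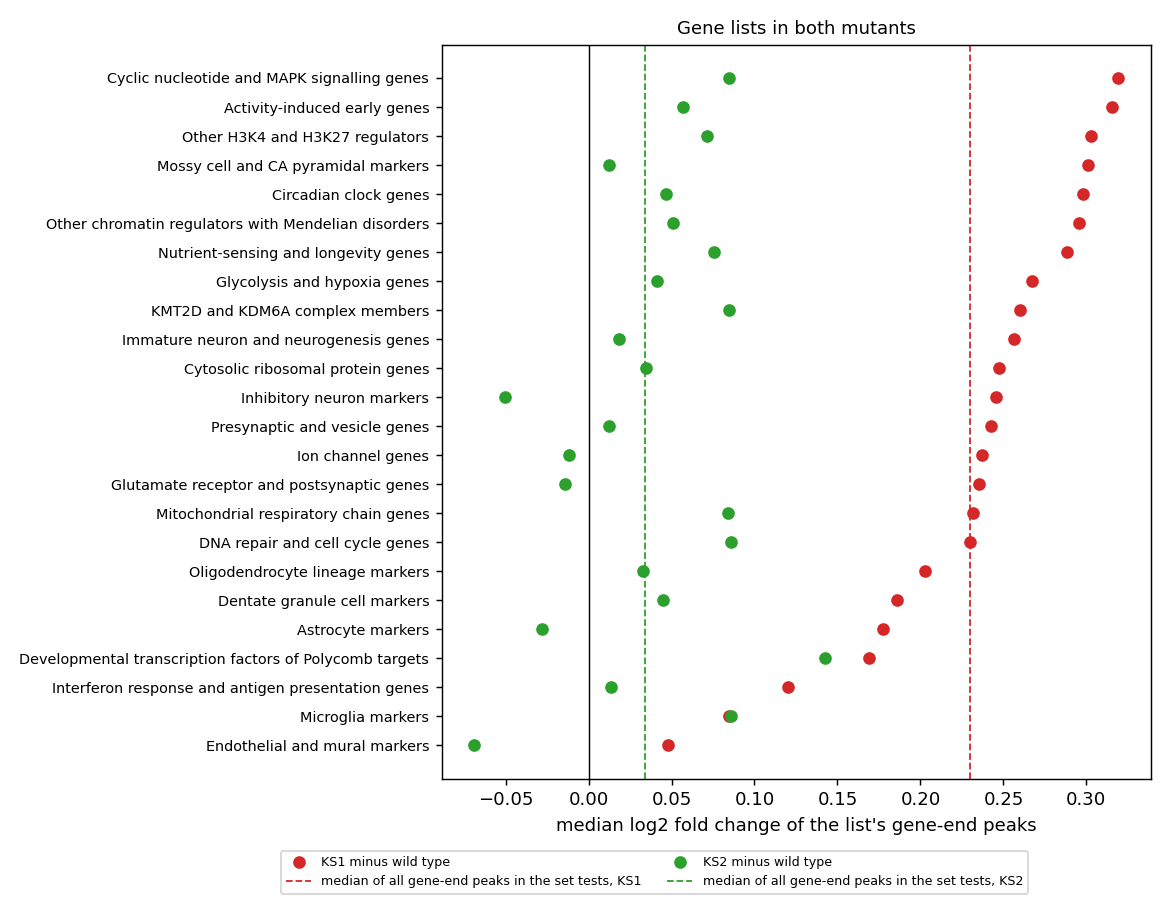
Median log2 fold change of the gene-end peaks of each of the 24 gene lists (horizontal axis) in KS1 and KS2 against their wild types; dashed lines mark the medians over all genes with an end peak, 0.23 in KS1 and 0.034 in KS2. All 24 lists had a positive median in KS1 and 19 had one in KS2.

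Peaks on chromosome X lay 0.039 above autosomal peaks in KS1 on the log2 scale (camera p = 0.0793, p = 0.304 with an estimated correlation). The value was 0.068 in cohort 9 (camera p = 0.00955) and -0.0098 in cohort 9_2 (camera p = 0.920), at the preset correlation.

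The second comparison asked the same of the Kdm6a mutation. No single region passed in KS2: of 164407 tested peaks, edgeR, DESeq2 and limma-voom with cyclic loess each called 0, with 4394, 3535 and 5297 peaks at an unadjusted p under 0.05. The values at the top of the ranking are given without a call. Onecut1 stood among them again, at the same gene-end peak as in KS1, with 26.5 ± 3.46 CPM in KS2 (SD, n = 4) against 14.2 ± 2.82 in wild type (n = 6). Its log2 fold change against the wild types of cohort 10-5 was 0.68 (SE 0.15, edgeR adjusted p = 1.00), and it was higher in 4 of 4 KS2 libraries. It passed over all peaks with 2 surrogate variables in place of the cohort (log2 0.70, edgeR adjusted p = 0.0354), with the top-peak share as a covariate (0.67, edgeR adjusted p = 0.0140) and without KS2 replicate 3 (0.74, edgeR adjusted p = 0.0286), and in no other setting, the lowest other adjusted p being 0.463 by DESeq2. A peak inside Tfap2a, a developmental transcription factor (chromosome 13, 40722605 to 40723549), had 13.6 CPM in KS2 and 6.06 ± 1.86 CPM in wild type (log2 0.93, SE 0.21). Other high values belonged to the end of 5730507C01Rik (log2 1.63, SE 0.31), a peak 334617 bp from Sema6d (1.08, SE 0.20), a peak near Pter (1.82), and the ends of Vmn1r205 (1.97), Il1rapl2 (0.59) and Taar7f (1.81). Low values belonged to peaks inside Clip1, a microtubule plus-end protein (log2 -0.79, SE 0.19), inside Abtb2 (-0.81) and Bcas3 (-1.89), near Sulf1 (-0.99), and at the ends of Kctd11 and Tmem95 (-0.80), Cacna1d (-1.02), Cep70 (-1.01), Tnfrsf1b (-0.79) and Smco3 (-0.54). Each had an edgeR adjusted p = 1.00. Simulated peaks changed by log2 of 1 and 2 were recovered in 17.9% and 62.1% of cases with the number and spread of these libraries. Those peaks had medians of 3.04 and 3.02 CPM. At such counts, changes of the size seen in KS1 were mostly not detectable here. Part of the spread came from KS2 replicate 3. Its Pearson correlation of log CPM with the other KS2 libraries was 0.749 to 0.792, against 0.924 to 0.955 among those. Without KS2 replicate 3, edgeR called 2 peaks, and 8538 had an unadjusted p under 0.05.

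No gene list passed in KS2 by camera, and fry called none, out of 24. Developmental transcription factors came closest, with 15 of 21 higher, a median of 0.14, and 1 member, Onecut1, past adjusted over the list alone (camera adjusted p = 0.166, adjusted p = 0.939 with an estimated correlation). Within cohort 10-5 alone this list passed, above other genes (median 0.19, camera adjusted p = 0.0136 at the preset correlation). Pax7 had a log2 fold change of 0.64 (SE 0.27) and Lhx3, whose end peak held 0.349 CPM in KS2, one of -1.56 (SE 0.63). Chromatin regulators of other Mendelian disorders were higher in 30 of 38 cases, respiratory chain genes in 35 of 43, KMT2D and KDM6A complex members in 6 of 8, and activity-induced genes in 17 of 27, with Homer1 at 0.18 and Klf4 at 0.20. Microglia markers included Spi1 at -0.55, mossy cell markers Bok at -0.38, and oligodendrocyte lineage markers Ermn at 0.89. Gene-end peaks lay 0.016 above the others (camera p = 0.320, p = 0.783 with an estimated correlation), and 0.020 above them within cohort 10-5 (camera p = 0.204), where the top 10% of peaks held 47.5 ± 2.84% of the counts in KS2 and 47.5 ± 0.434% in wild type. The excess turned past the threshold, at the preset correlation, without KS2 replicate 3 (0.11, camera p = 5.1e-10) and without wild-type replicate 1 (0.057, camera p = 0.00147). It was -0.031, -0.014 and -0.015 without KS2 replicates 1 and 4 and wild-type replicate 3. Peaks on chromosome X lay 0.21 above autosomal peaks (camera p = 6.7e-09, p = 0.257 with an estimated correlation), and 0.19 above them within cohort 10-5 alone. Without KS2 replicate 3, in which chromosome X held 2.83% of the counts against 1.92% to 2.15% in the other KS2 libraries, the value was 0.063 (camera p = 0.333 at the preset correlation), and without wild-type replicate 1 it was 0.12. With the log2 total count as a covariate, a setting added after the data were seen, the chromosome X value turned to -0.040 (camera p = 0.155 at the preset correlation) and the gene-end excess was 0.15 (camera p = 7.5e-10).

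The third comparison asked whether the mutations differ in effect, in 1 model over all 23 libraries. Of 171729 tested peaks, edgeR and DESeq2 each called 0, with 8330 and 8125 at an unadjusted p under 0.05. Higher in KS1 relative to KS2, without passing, were a peak inside Plekha6 (log2 difference 1.33, SE 0.31), both peaks of the kappa locus (1.07 and 1.17), a peak inside Mvb12b (1.22), and the ends of Bok (0.65), Camk2d (0.61, SE 0.18), Tmem135 and Fzd4 (0.62), Kctd11 and Tmem95 (0.79) and Sowahb (1.13). Lower were peaks near Dph6 (-1.56, SE 0.34), Spry2 (-3.33) and Htr1a (-1.92), inside Ptprg (-2.49) and Mettl25 (-1.55), and at the ends of Wdfy3 (-0.79), Mcf2 (-0.83), E030030I06Rik (-1.01), Vmn1r5 (-2.10) and Exph5 (-1.59). Each had an edgeR adjusted p = 0.933. By class, the KS1 effect exceeded the KS2 effect at gene ends by 0.20 relative to other peaks (camera p = 6.0e-14, p = 0.0569 with an estimated correlation). Of the 24 lists, developmental transcription factors alone differed, with a median difference of -0.050 against 0.18 over all genes with an end peak (camera adjusted p = 7.1e-06, adjusted p = 0.140 with an estimated correlation).

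The last comparison asked whether the same regions move in both mutants, which share no wild-type library. As edgeR called 0 peaks in KS2, no called peak was shared, at an adjusted p under 0.05 or under 0.1, or by DESeq2. With 2 surrogate variables in place of the cohort in both fits, the end of Onecut1 passed in KS1 (edgeR adjusted p = 2.9e-05) and in KS2 (edgeR adjusted p = 0.0354). Without the cohort term, that KS2 difference can also draw on the wild types of cohort 8. This peak had 11.1 to 12.6 CPM in those wild types and 14.8 to 18.2 CPM in the wild types of cohort 10-5. Of the 16 peaks called in KS1, 15 were tested in KS2, and 10 of these had the same direction. When KS2 p-values were adjusted over these 15 peaks alone, a step chosen after the KS1 calls were seen, 3 passed: the end of Onecut1 (adjusted p = 0.00386 from the edgeR p), the peak 12124 bp from it (log2 0.66 in KS2, adjusted p = 0.0278 from the edgeR p) and the end of Adgrl2 (log2 0.44 in KS2, adjusted p = 0.0278 from the edgeR p). Fbn2 (log2 0.37 in KS2), Zfp521 (0.31) and Camk2d (0.27) did not pass. Of the 751 peaks with an adjusted p under 0.1 in KS1 that were tested in both, 561 (74.7%) had the same direction in KS2, 77.7% at gene ends and 68.5% elsewhere, where all peaks tested in both had 52.3%. For gene ends a nearer baseline is 57.2%, the share of all gene-end peaks that were higher in KS2. Of the 503 gene-end peaks at that threshold in KS1, 500 were higher. Over all 159896 peaks tested in both, log2 fold changes had a Pearson correlation of 0.020 and a Spearman correlation of 0.047 across peaks, which are not independent replicates. Among peaks with an unadjusted p under 0.01 in each, 15 were higher in both against 6.28 for independent lists (Fisher's exact 1-sided p = 0.00173), and 6 were lower in both against 2.15 (p = 0.0218). At an unadjusted p under 0.05 the shared peaks were 131 higher against 157 (Fisher's exact 1-sided p = 0.989) and 137 lower against 79.0 (p = 5.9e-10). These counts depend on the setting. Without the cohort in the models, 738 higher peaks were shared at an unadjusted p under 0.05 against 208 (Fisher's exact 1-sided p = 4.6e-209), and with no filter 18 at an unadjusted p under 0.01 against 12.5 (p = 0.0797).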

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

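Of the tests in this part, the correction for total count, the fit without KS2 replicate 3 and the covariates of counts in the top 10% of peaks, over all or distal peaks, were chosen only after the result was seen.

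Gene-end peaks lay 0.22 above other peaks in KS1, and the KS1 effect there exceeded the KS2 effect by 0.20, which rests on a KS2 excess of 0.016 that was 0.11 without KS2 replicate 3 (camera p = 5.1e-10 at the preset correlation). Of 40 splits of the libraries within their cohorts, drawn from 525, 1 gave an excess as large, the real one (highest other 0.18). This argues against chance alone but cannot exclude it, as 40 splits allow no lower rank and the split tests were not adjusted. With the log2 total count as a covariate the excess was 0.22. In cohort 9_2, however, the totals separate the genotypes, at 12.5 to 16.6 M in KS1 and 8.75 and 6.98 M in wild type. A covariate with a slope common to both cohorts therefore cannot exclude a difference in library size. A difference in enrichment between libraries stays open: with the share of distal counts in the top distal peaks as a covariate, the excess was 0.088 (camera p = 6.1e-08, p = 0.106 with an estimated correlation), and with the share over all peaks 0.019. In cohort 9_2 that share separates the genotypes, at 50.4 ± 0.910% (SD, n = 4) and 44.2 ± 0.313% (n = 2), so such a covariate can also remove an effect of genotype, and a gain at gene ends would itself raise the share. An effect of the Kmt2d mutation on gene ends may therefore be present, and these libraries do not separate it from enrichment or library size.

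Peaks on chromosome X lay 0.21 above autosomal peaks in KS2, and the KS1 effect minus the KS2 effect was -0.18 (camera p = 7.0e-04, p = 0.358 with an estimated correlation). Chance cannot be excluded, since 13 of the 35 splits within cohort 10-5 gave a shift as large in size (highest other -0.37). That 1 library stands apart is a candidate explanation: without KS2 replicate 3 the shift was 0.063 (camera p = 0.333 at the preset correlation), and that library held 2.83% of its counts on chromosome X against 1.92% to 2.15% in the other KS2 libraries. The chromosome X share of KS2 replicate 3 was not among the values flagged as far from the rest. With the log2 total count as a covariate the shift was -0.040, and without wild-type replicate 1, the deepest library, it was 0.12. With the top-peak share as a covariate the shift stayed at 0.22 (camera p = 2.1e-10 at the preset correlation). A biological shift through the loss of X-linked Kdm6a stays open and was not tested, and the labels give no sex.

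The share of counts at gene ends was 29.9% in KS2 replicate 3 and 33.7% to 34.3% in the other KS2 libraries. Wild-type replicate 1 of the KS2 comparison had a total of 19.4 M, and the others had 6.59 to 11.2 M. At the peak 12124 bp from Onecut1 (chromosome 9, from 74848466), wild-type replicate 2 of the KS1 comparison had 3.12 CPM, and the other wild types had 5.84 to 6.79 CPM. Of 86 groups of values tested for a sample far from the rest, these 3 had one, where chance gives about 1 in 20.

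The KS1 and KS2 effects also differed at intergenic peaks, by -0.11 relative to other peaks (camera p = 0.00566, p = 0.155 with an estimated correlation). Developmental transcription factors differed with a median of -0.050, where all genes with an end peak had 0.18 (camera adjusted p = 7.1e-06, adjusted p = 0.140 with an estimated correlation). In KS1 camera placed this list above other genes in cohort 9 and below them in cohort 9_2.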

How the results depend on the processing

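Alternatives named as added in the account of the processing were chosen only after the data were seen, as were all settings for classes, lists and chromosome X beyond the cohort, leave-out, RLE, loess and summed-count settings. Corrections for GC content, the replicate block with such a correction and other CpG island definitions were not run. Where no construction of the alternative shows it, the cause was not tested.

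Calls in KS1 (16) numbered 42 with 2 surrogate variables, 27 among autosomal peaks, 2 with cyclic loess, 6022 by DESeq2, 172 with the log2 total count, 4 without the cohort, 0 in cohort 9 alone, 9109 in cohort 9_2 alone, 758 at an adjusted p under 0.1, and by edgeR 0 with the top-peak share (8121 with an unadjusted p under 0.05) and 0 with its distal form (7817), and 3 to 1413 without 1 library. For DESeq2, 142116 of 166596 peaks had no adjusted p through its filter on low means. Counts summed per gene gave 4 genes, all lower. With the replicate number as a block in place of the cohort, although replicate numbers do not pair these libraries, the count was 1110. In KS2 (0) they numbered 11 with surrogate variables, 7 with the top-peak share and 0 to 2 without 1 library. Of the 16 peaks, Camk2d passed in 25 of 27 settings, the kappa peak at 68152171 and the Scaf11 peak in 24, the ends of Onecut1 and Zfp521 in 20, Foxp2 in 19, and Nell2 and Vdr in 11; none turned direction.

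The KS1 gene-end excess was 0.019 with the top-peak share; over its other alternatives it was positive and passed at the preset correlation, at 0.062 with cyclic loess and 0.088 with the distal share (p = 0.106 with an estimated correlation). The KS2 excess was 0.25 without the cohort, 0.15 with the log2 total count, 0.15 with the replicate block, 0.064 with surrogate variables, all past the threshold at the preset correlation, and -0.031 to 0.11 without 1 library. KS1 lists (10) numbered 0 with cyclic loess, 4 with surrogate variables, 4 in cohort 9, 5 in cohort 9_2, 1 with the top-peak share and 5 to 12 without 1 library. KS2 lists (0) numbered 13 without the cohort, 1 in cohort 10-5 (developmental transcription factors), 1 with surrogate variables, 1 with the log2 total count, 2 with the replicate block and 0 to 1 without 1 library. The KS1 shift of chromosome X was 0.068 in cohort 9, -0.0098 in cohort 9_2, 0.074 with surrogate variables, 0.053 with cyclic loess, 0.041 with total-count scaling, 0.085 with the top-peak share and 0.011 to 0.057 without 1 library; it passed at the preset correlation, as the reported value did not, in all of these but cohort 9_2 and most fits without 1 library. The KS2 shift was 0.016 without the cohort, turned to -0.040 with the log2 total count, neither passing, and was 0.063 to 0.29 without 1 library. The Kdm6a end peak passed in KS1 in 3 alternatives, among them DESeq2 (0.33), and not in 12, and ran from 0.28 to 0.40 over them. The difference between KS1 and KS2 stayed at 0 calls by edgeR and DESeq2 in 28 alternatives, with 8330 and 8125 peaks at an unadjusted p under 0.05, and shared calls at 0 in 4. In each of those 4, KS2 had 0 calls. With 2 surrogate variables in place of the cohort the end of Onecut1 passed in both mutants (edgeR adjusted p = 2.9e-05 in KS1 and 0.0354 in KS2).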

Other observations

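Of the tests in this part, those on neighbourhoods of called peaks and on the region around Kmt2d, and the share of KS1 peaks moving the same way in KS2, were chosen only after the results were seen; the splits of the samples were not.

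Neighbourhoods of called peaks were tested at 4 places. Of 28 peaks tested within 100 kb of Onecut1 in KS1, 17 were higher (median log2 fold change 0.045) and 8 passed adjusted over the region alone, 7 of them higher, including the 2 called peaks that prompted the test. In KS2, of 28 tested peaks 22 were higher (median 0.24) and 3 passed adjusted over the region alone, all higher. A high share of higher peaks is no sign of a local gain: within 100 kb of Foxp2 37 of 43 were higher in KS2 (median 0.26), and edgeR called 0 adjusted over the region alone (1 with an unadjusted p under 0.05). In KS1 1 of 36 peaks around Foxp2 and 2 of 36 around Camk2d passed adjusted over the region alone, each including 1 called peak, and in KS2 0 of 36 around Camk2d did (2 with an unadjusted p under 0.05). Over the immunoglobulin kappa locus 62 of 81 peaks were higher in KS1, with a median log2 fold change of 0.28, and 11 passed adjusted over the region alone, all higher and again including 2 called peaks; in KS2 51 of 89 were higher and edgeR called 0 adjusted over the region alone (2 with an unadjusted p under 0.05).

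Low p-values in KS1 were frequent around the mutated gene. Of the 16 called peaks, 5 lie within 20 Mb of Kmt2d on chromosome 15 (0.227 would be there by share of tested peaks), namely those near Pick1 and Scaf11 and inside Nell2, Vdr and Abcd2. Of the 2361 peaks in that window 1.69% had an unadjusted p under 0.001 against 0.836% elsewhere on the autosomes, and 0.736% of 2447 such windows had a share as high. Such windows overlap heavily, so this percentage is a rank and not a p-value. Of the 18 windows as high, 8 lay on other chromosomes. By cohort the percentage of windows as high was 0.123% in cohort 9 and 11.9% in cohort 9_2, so the window does not stand out among others in cohort 9_2. With gene-end peaks left out and both cohorts together, 1.11% of 1979 peaks in the window were below 0.001, against 0.322% elsewhere. Then 1 of 2442 windows was as high and 0 lay on other chromosomes, though the 5 called peaks that prompted the test are included. Kmt2d lies near the end of chromosome 15, so its window is shorter than most. DNA linked to the mutated gene, kept from the strain in which the insertion was made, is a candidate explanation. Enrichment is argued against as the whole cause, since with the top-peak share as a covariate the window still differed (Fisher's exact 1-sided p = 5.2e-04). That test rests on 8 of 2361 peaks, which include the called peaks near Pick1 and Scaf11 and inside Abcd2 that prompted it. At an unadjusted p under 0.05, KS2 had 1.87% of peaks in the window and 2.61% elsewhere (Fisher's exact 1-sided p = 0.991), and KS1 17.5% and 12.1%. As only 2.67% of all KS2 peaks were below 0.05, KS2 cannot tell whether the region would differ in any mutant. At an unadjusted p under 0.001 KS2 had 0 peaks in the window and 0.00887% elsewhere, too few to tell.

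Other splits of the libraries within cohorts were fitted for each count. In KS1 3 of 40 splits called as many peaks as the real 16 (highest other 464), so chance cannot be excluded for the count. Why some splits had many times more calls was not tested. For the 10 lists past camera at the preset correlation 1 of 40 splits, the real one, gave as many (highest other 8), which argues against chance for that count alone. None of these lists passed with an estimated correlation, and the count was 0 with cyclic loess and 5 without wild-type replicate 3 of the KS1 comparison. For chromosome X in KS1 17 of 40 splits gave a shift as large in size as 0.039 (highest other -0.073), so chance cannot be excluded. In KS2 33 of 35 splits gave a gene-end difference as large in size as 0.016 (highest other 0.24), so chance cannot be excluded, nor can it for the Spearman correlation between KS1 and KS2 fold changes of 0.047, which 8 of 35 splits reached (highest other 0.11). For the share of KS1 peaks with an adjusted p under 0.1 moving the same way in KS2, 74.7%, 1 of 35 splits reached it, the real one (highest other 71.9%). A rank of 1 among 35 or 40 splits argues against chance but cannot exclude it. The margin of this share is narrow and not kept under all settings, for which the splits were not refitted. The share was 68.8% with cyclic loess, 68.6% with the top-peak share as a covariate, 63.7% and 71.1% without KS2 replicates 1 and 4, and 68.8% and 71.9% without wild-type replicates 2 and 3 of the KS2 comparison. It was 72.1% without KS2 replicate 2, 75.6% with 2 surrogate variables, 80.4% by DESeq2 and 91.3% without the cohort. It was 75.5% without each of wild-type replicates 4, 5 and 6 of that comparison, 84.6% without KS2 replicate 3 and 83.8% without wild-type replicate 1. Every split reaches a count of 0, so the splits say nothing about chance for the 0 peaks called by edgeR in KS2 (35 of 35, highest other 7093), the 0 lists in KS2 (35 of 35, highest other 2) and the 0 peaks called by edgeR for the difference (24 of 24 drawn from 18375, highest other 1463). Why some of these splits called many peaks was likewise not tested.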
